A study of Triticum aestivum with 107 samples.

How the data were processed

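Shoots of wheat seedlings were profiled on a small spotted oligonucleotide array after inoculation with the stripe rust fungus Puccinia striiformis f. sp. tritici (Pst) or after mock treatment with talc that carried no spores. The 9 genotypes were the susceptible spring wheat Avocet (AVS) and 8 near-isogenic lines, each of which carries a single all-stage resistance gene (Yr01, Yr05, Yr07, Yr08, Yr09, Yr10, Yr15 or Yr17) brought into AVS by 6 backcrosses. Per the labels, each RNA sample came from 6 pooled seedlings, and samples were taken at 24 h, at the end of a cold dark period with dew, and at 48 h, after transfer to a growth chamber with light. The lines were inoculated with isolates avirulent on them (number 45 on Yr01 and Yr07, number 78 on Yr05 and Yr15, number 21 on Yr08, Yr09, Yr10 and Yr17), and AVS with isolate 78, which is virulent on it. Arrays of virulent isolates on the lines were not analysed here. Groups were taken from the sample titles, which gave 36 groups of 3 biological replicates each, except AVS mock at 24 h with 2, for 107 arrays in all.

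Each array was deposited as a table of spot intensity values from a spot-finding program, with the mean and median brightness of the spot and of its local background on a 16-bit linear scale that ends at 65535, per the file headers. The program, the scanner and its settings were not given in the sources used here. The red and green columns were identical on every array, so that 1 colour was measured. The authors also deposited a table of log2 values for the same arrays, made with affy per the submitters' processing notes (version not given in the sources used here). Its columns all had a median of 12.77 and ranked the spots of each array almost as spot mean minus background did (lowest rank correlation 0.998), so these log2 values were background-subtracted and quantile normalized as far as the values tell. They served as an alternative.

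Every array held 841 spots. After normexp background correction of the spot mean against the local background median (offset 50), 131 control spots were left out (117 background spots, 8 of bacterial transcripts, 4 biotin controls and 2 of blank buffer). The 710 spots left were quantile normalized between arrays on the log2 scale and the 2 spots of each probe were averaged, which left 355 probes. Of these, 343 were panel probes that earlier work on the genes Yr5 and Yr39 had selected, and 12 were wheat reference probes. The array is therefore a selected panel and no survey of the genome. Gene names and functional categories are those written in the probe names of the files. They name 192 of the 343 panel probes, and the others are marked as without homology (101), as hypothetical (33) or as not found (17). Probes are named below by these descriptions, without their probe-set identifiers, and several probes can carry the same description. The gene table at hand could not be matched to these probe-set identifiers, so that no coordinates are given. A probe counted as detected on an array where its signal lay above the 95th percentile of that array's background spots. Blank buffer spots also passed that bound on 85 of 107 arrays, so that detection does not by itself show wheat transcript. Detection covered 213 to 350 of the 355 probes per array (median 311). At the upper end, 0 to 25 probes per array were saturated (median 3). Duplicate spots of a probe correlated at a median of 0.954 per array. The number of arrays limits the precision of every value below.

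Tests were made with limma 3.58.1 in R 4.3.3, with a mean for each of the 36 groups over all 107 arrays, moderated errors with an intensity trend, and Benjamini-Hochberg adjustment over the 355 probes within each comparison. A probe passed at an adjusted p under 0.05. The comparisons were inoculated against mock within each genotype and time, the mean of these responses over the 8 lines, the differences of responses between the lines and AVS, among the lines and between the times, mock at 48 h against mock at 24 h over the 9 genotypes, and the mock arrays of each line against those of AVS. Errors are standard errors (SE) of the fit unless stated. Gene lists were matched to the probe descriptions by words and tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. Lists with fewer than 3 members on the panel were counted and not tested. The word match took neither the probes spelled on the array as phenylalanine-ammonia lyase nor PR protein 1 and PR protein 10 into any list. It put a methionine-S-oxide reductase into the PR list, 2 ABC transporters and a Cf2/Cf5 homolog into the NBS-LRR list and shikimate kinase into the kinase list, while the 14 members of the oxidative list include blue copper-binding proteins. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

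The comparisons, the gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. By that rule a probe with a gene name could be named, with 1 probe per gene name, that of smallest adjusted p. For the mean of the 8 lines the rule took up to 12 higher and 8 lower probes by size of change, among those that passed and went the same way in at least 7 of the 8 lines. In AVS it took up to 12 higher and 8 lower, and in single lines 2 higher and 1 lower, among those that passed with no overlap between inoculated and mock arrays. Up to 6 in each direction were taken for differences between responses, up to 5 in each direction for mock at 48 h against 24 h, and up to 2 in each direction for each line's mock arrays. From each gene list the 3 members of smallest adjusted p at each time could be named, and all members of the list of transcripts named by the study. Any probe outside the rule is said to have been chosen after its values were seen.

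The fit was tested on simulated data drawn from each probe's mean over all arrays and its residual spread, with 90 of the 355 probes changed. The simulated probes varied independently, without differences between genotypes, times or replicates. The shares of false calls below therefore do not cover probes that vary together. For the mean of the 8 lines at 24 h it recovered 64.2% of changes of 0.5 on the log2 scale, 95.3% of changes of 1 and 99.8% of changes of 2, and 4.01% of its calls were false. For a single line, simulated as Yr08 at 24 h, it recovered 11.5%, 35.7% and 79.5%, with 4.68% false calls. For mock at 48 h against 24 h it recovered 69.7%, 94.8% and 100%, with 2.58% false calls. A shifted list of 14 probes was called by camera in 20 of 20 simulations and an unshifted list in 0 of 20.

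Alternatives tried were no background correction, median centring or cyclic loess in place of quantile normalization, the deposited log2 values, the median of the 2 spots, leaving out the dimmest probes, which kept 237 of 355, a log2 change of at least 1 as a further condition, only the arrays compared in the fit, the replicate number as a block, the flat as a block, and each replicate left out in turn. The median of 2 spots equals their mean, so that this alternative tests nothing. Samples of 24 h and 48 h with the same replicate number came from 1 flat, which the main fit does not model. With the flat as a block (consensus correlation 0.043) all 38 counts stayed within 1.5 times. The replicate numbers did not pair the arrays by the test set for it, so that fits with that block appear only among the alternatives. Still, 85 of 107 arrays correlated best with arrays of their own number, so that a batch by number may remain in the main fit. Added after seeing the data were the position of the array on the slide as a block, the replicate number within each time as a block, array brightness as a covariate, array weights, leaving out the array with the poorest duplicate spots, leaving out the line Yr08, the probe classes written in the probe names, and gene lists with these word matches corrected by hand, the oxidative list left as it was. Each slide carried arrays at 4 positions, but which arrays shared a slide was not given in the sources used here.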

Results

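The arrays covered shoots of AVS and of 8 near-isogenic lines at 24 h and 48 h after inoculation or mock treatment, with 54 inoculated and 53 mock arrays. Each group had 3 biological replicates, except AVS mock at 24 h with 2. The median spot brightness of an array ranged from 1534 to 48416 on the scanner scale (median 16180), and 213 to 350 of the 355 probes per array lay above background. Arrays of the same group correlated at a median of 0.905 and arrays of different groups at 0.826. The leading principal component carried 28.5% of the variance and followed the time of sampling (squared correlation 0.725). Array brightness differed with treatment, at a mean log2 of 14.35 in the inoculated and 13.73 in the mock arrays of the lines at 24 h, and of 14.15 and 13.47 at 48 h.

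Inoculated and mock plants of the lines were compared to ask which transcripts respond when a resistance gene meets an isolate it recognizes. Averaged over the 8 lines at 24 h (24 inoculated against 24 mock arrays), 42 probes rose and 37 fell. The steepest rise among named transcripts was that of an NB-ARC domain containing protein, of the class of intracellular immune receptors, by 1.99 ± 0.39 on the log2 scale (3.98-fold). A heat-stress transcription factor, which drives heat shock genes, rose 2.63-fold (log2 1.40 ± 0.18). Phenylalanine ammonia-lyase, the entry enzyme of the phenylpropanoid pathway, rose by 1.38 ± 0.21 on the log2 scale, and the probe spelled phenylalanine-ammonia lyase by 1.07 ± 0.17. All 4 were higher in 8 of 8 lines, with adjusted p between 9.11e-05 and 1.86e-08.

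Further probes that rose in 8 of 8 lines at 24 h were a blue copper-binding protein (log2 1.34 ± 0.22), a putative disease resistance protein (1.31 ± 0.31), reticuline oxidase of alkaloid synthesis (1.25 ± 0.20), a peroxidase (1.16 ± 0.19), alternative oxidase of the mitochondrial electron transport chain (1.07 ± 0.23), a histidine amino acid transporter (1.02 ± 0.24) and a calmodulin-binding heat shock protein (0.95 ± 0.19). An extracellular glycoprotein with leucine-rich repeats rose by 0.98 ± 0.30 and was higher in 7 of 8 lines (adjusted p = 0.0113). The responses of single lines spread widely around these means. For phenylalanine ammonia-lyase they ran from 0.33 in Yr10 to 2.20 in Yr08, and for the putative disease resistance protein from 0.18 in Yr15 to 3.81 in Yr08. Probes that fell did so by less. A hydroxyproline-rich glycoprotein fell by 0.92 ± 0.29 (adjusted p = 0.0131). Without Yr08 and Yr09, where its signal was uneven between arrays, it stood at -0.52 ± 0.33, a choice made after its values were seen, so that its fall is not shown to follow inoculation. Lower by at least 0.64 were also the transcription factor WRKY5, an NBS-LRR disease resistance protein, an aspartyl protease, a mitogen-activated protein kinase, a beta-1,3-glucanase, a metallothionein and an NAD dependent epimerase. WRKY5 fell by 0.77 ± 0.23, the NBS-LRR protein by 0.77 ± 0.20 and the aspartyl protease by 0.69 ± 0.16, each in 8 of 8 lines.

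**Figure D1:**
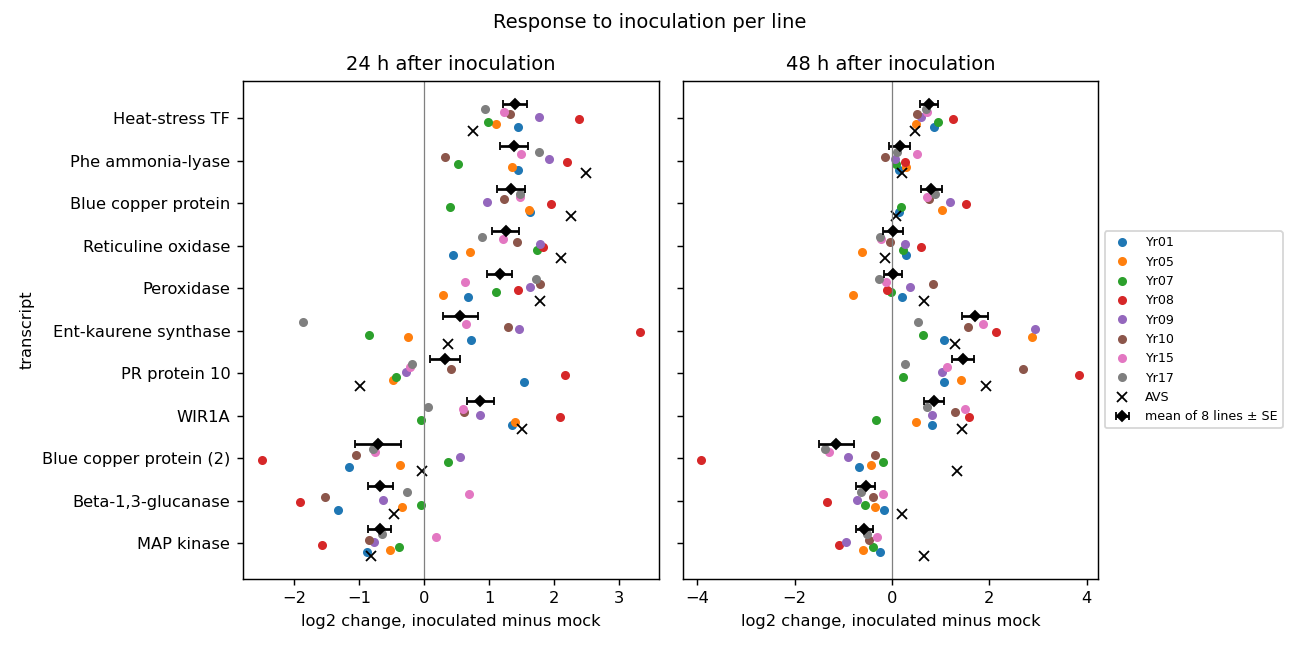
Log2 change, inoculated minus mock, of 11 transcripts per line (coloured dots), in AVS (crosses) and as the mean of the 8 lines ± SE (diamonds), at 24 h on the left and 48 h on the right. At 24 h the dots of the heat-stress transcription factor run from 0.93 to 2.38, and at 48 h those of ent-kaurene synthase from 0.54 to 2.93.

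Without Yr08, the line with the most changed probes, 50 probes passed at 24 h, and the extracellular glycoprotein, the hydroxyproline-rich glycoprotein, WRKY5 and the beta-1,3-glucanase were no longer among them. Leaving out replicate 1 or replicate 2 of every group left 41 and 35, leaving out the dimmest probes left 49, and with array brightness as a covariate 121 passed. With arrays centred on their median in place of quantile normalization, 32 probes were higher and 161 lower while the median of all probes fell by 0.45, so that directions are relative to the panel. The heat-stress transcription factor, both phenylalanine ammonia-lyase spellings, alternative oxidase, reticuline oxidase, the peroxidase, the blue copper-binding protein and the NB-ARC protein passed under every alternative run on them. Arrays lay at 4 positions of their slides. With the position as a block 77 of the 79 probes passed and the heat-stress transcription factor stood at 1.42 ± 0.18. Positions 1 to 4 each held 9 to 14 of these arrays, with both treatments in 2, 4, 2 and 3 lines. Within them 59, 78, 77 and 76 of the 79 probes had the pooled direction. Such agreement is partly built in, since the pooled direction was taken from the same arrays. The heat-stress transcription factor rose within these positions by 0.16 ± 0.50, 2.15 ± 0.49, 1.86 ± 0.73 and 1.28 ± 0.44.

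The gene lists were mixed at 24 h. Of 14 phenylpropanoid and lignin probes, 4 rose, all phenylalanine ammonia-lyases with changes from 0.42 to 1.92 ± 0.50, 1 fell, a dirigent-like protein of lignan formation (-0.61 ± 0.16), and 9 did not pass (camera adjusted p = 0.277). Of 12 probes that the word match put in the NBS-LRR resistance list, 2 of which are ABC transporters, 3 rose and 2 fell, among the latter a homolog of the tomato receptors Cf2 and Cf5, which carry no nucleotide-binding domain (-0.58 ± 0.14; camera adjusted p = 0.301). Of 14 oxidative burst and redox probes, 4 rose and 3 fell, the latter including superoxide dismutase, which removes superoxide (-0.42 ± 0.08; 0.746). Of 5 transcription factors, the heat-stress factor and a basic helix-loop-helix protein (0.80 ± 0.24) rose and WRKY5 fell (0.327). Of 23 probes that the word match put in the pathogenesis-related (PR) list, which took in a methionine-S-oxide reductase and missed PR protein 1 and PR protein 10, WIR1A, a wheat cell wall protein induced by pathogens (0.86 ± 0.21), and a beta-1,3-glucanase, which cleaves fungal wall glucan (0.84 ± 0.22), rose and another beta-1,3-glucanase fell (0.553). Kinases and receptors had 4 higher and 3 lower of 24 (0.688), and transport 3 higher and 2 lower of 17 (0.567).

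Calcium signalling had 1 higher of 6 probes, the calmodulin-binding heat shock protein (camera adjusted p = 0.301), and terpenes and cytochrome P450 1 higher of 8 (0.514). Protein turnover had 2 aspartyl proteases lower of 7 (0.176), cell wall 1 lower of 6 (0.277) and amino acid metabolism 0 of 3 (0.777). Of the 4 reference genes, probes of GAPDH (-0.51 ± 0.16) and actin (-0.42 ± 0.14) fell under quantile normalization and stayed below 0 under every other scaling (0.176). The 12 transcripts named by the study stood above the other probes (camera adjusted p = 0.0388), with 4 higher and 0 lower by limma and 6 of the 12 at an adjusted p under the threshold over the list alone. That call was lost with an estimated correlation (adjusted p = 0.194), and a list the study drew from these arrays is not independent evidence of its direction. Adjusted over the list alone, the reference genes had 3 lower and the other lists the same counts. The median lay below 0 while the mean and the camera direction lay above it for the PR list, oxidative burst, transcription factors and transport. Lists with 1 or 2 probes were not tested. The heat shock list's 1 probe rose, while jasmonate, carbohydrate, ribosome, photosynthesis, and cold and dehydration probes did not pass, and no probe matched the circadian or the fungal list.

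At 48 h, in the light, 28 probes rose and 15 fell in the mean of the 8 lines (24 inoculated against 24 mock arrays). Ent-kaurene synthase, which makes a diterpene precursor of gibberellins and of cereal phytoalexins, rose 3.26-fold (log2 1.70 ± 0.27, adjusted p = 2.61e-06) and was detected on 22 of 24 inoculated and 9 of 24 mock arrays. Its log2 change ran from 0.81 to 2.87 across the alternatives, so that its size depends on the processing. PR protein 10, a small intracellular defence protein, rose 2.74-fold (1.45 ± 0.23, adjusted p = 2.61e-06). Both were higher in 8 of 8 lines, ent-kaurene synthase by 0.54 in Yr17 to 2.93 in Yr09 and PR protein 10 by 0.22 in Yr07 to 3.85 in Yr08. The extracellular glycoprotein (1.11 ± 0.30), a UDP-glucosyl transferase (0.92 ± 0.24), WIR1A (0.86 ± 0.21) and the heat-stress transcription factor (0.76 ± 0.18) rose as well, with adjusted p from 0.00495 to 0.00913.

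Other rises at 48 h were those of a blue copper-binding protein (0.80 ± 0.22), a protein kinase (0.66 ± 0.18), a cytochrome P450 (0.57 ± 0.18), a beta-1,3-glucanase (0.55 ± 0.15) and UDP-glucose dehydrogenase (0.52 ± 0.17), each higher in at least 7 of 8 lines. A peroxidase rose by 0.69 ± 0.15 with 6 of 8 lines higher. Another blue copper-binding protein fell by 1.14 ± 0.35 in 8 of 8 lines, most in Yr08 (-3.91), while its value in AVS was 1.33 ± 1.00. The mitogen-activated protein kinase fell by 0.57 ± 0.18 and a beta-1,3-glucanase by 0.54 ± 0.19, both in 8 of 8 lines. Smaller falls in at least 7 lines were those of a WIR1A homolog (-0.38 ± 0.10), a hydroxyproline-rich glycoprotein (-0.31 ± 0.10) and reference probes of GAPDH (-0.36 ± 0.12) and EF1A (-0.28 ± 0.09), which were detected on 8 of 24 inoculated arrays. WIR1B (0.37 ± 0.10) and chitinase, which cleaves fungal chitin (0.35 ± 0.09), rose under quantile normalization, whereas with median centring they stood at -0.25 and -0.20 while the median of all probes fell by 0.37.

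**Figure D2:**
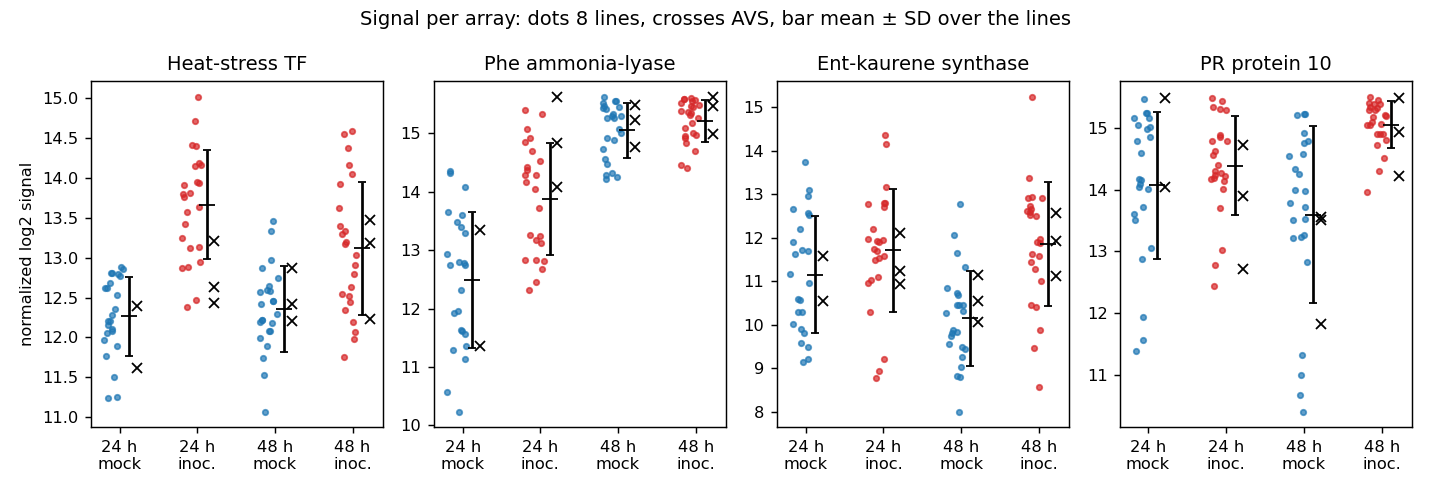
Normalized log2 signal of 4 transcripts on every array, with the 8 lines as dots (24 per group), AVS as crosses and the mean ± SD over the lines as bars. The mock arrays of phenylalanine ammonia-lyase lie higher at 48 h than at 24 h. At 48 h the means of PR protein 10 and ent-kaurene synthase over the lines lie higher in inoculated than in mock arrays.

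The calls at 48 h were fewer and less stable. Without Yr08 15 probes passed, and both blue copper-binding proteins, the cytochrome P450, the beta-1,3-glucanases, the mitogen-activated protein kinase, the hydroxyproline-rich glycoprotein and the reference probes were no longer among them. Only ent-kaurene synthase (1.41) and PR protein 10 (1.53) passed without replicate 2 of every group. The count was 26 without replicate 1 and 79 without replicate 3, and with median centring 18 probes were higher and 127 lower. With the position as a block ent-kaurene synthase stood at 1.58 ± 0.28 and PR protein 10 at 1.34 ± 0.23. Of the 43 probes, 42, 34 and 36 had the pooled direction within positions 1, 3 and 4, and position 2 held no line with both treatments. The pooled direction was again taken from the same arrays, so that this agreement is partly built in.

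By list at 48 h, the PR list had 6 of 23 higher and 3 lower (7 and 5 adjusted over the list alone; camera adjusted p = 0.472). The higher ones were WIR1A, WIR1B, chitinase and 3 beta-1,3-glucanases, and the lower ones included a thaumatin-like protein (-0.33). Of 8 terpene and cytochrome P450 probes, ent-kaurene synthase and 2 cytochromes P450 (0.57 and 0.82) rose (camera adjusted p = 0.0842). Kinases and receptors had 3 higher and 1 lower of 24 (4 and 1 adjusted over the list alone; 0.472), and oxidative burst 2 higher and 1 lower of 14 (3 and 2; 0.996). Transcription factors had 1 higher of 5 (2 higher and 1 lower over the list alone; 0.529), cell wall 1 lower of 6 (0.849) and reference genes 2 lower of 4 (3; 0.124). Phenylpropanoid (0.996), NBS-LRR (0.559), calcium (0.472), transport (0.472), protein turnover (0.161) and amino acid (0.996) lists had 0 probes past the limma threshold and no camera call. The list named by the study had 5 higher and 2 lower of 12 (6 and 3 adjusted over the list alone; 0.0842). Of the lists with 1 or 2 probes none had a call at 48 h, except that 1 of 2 cold and dehydration probes was higher adjusted over the list alone. The PR list and kinases had a median below 0 beside a mean and a camera direction above it, and in the oxidative list the median and mean lay below 0 while camera pointed up.

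The responses at the 2 times were set against each other to see which were early and which late. In the mean of the lines the response of 15 probes differed between 48 h and 24 h (6 higher, 9 lower; 96 arrays, with both times sampled from the same flats). PR protein 10 responded more at 48 h, by 1.14 ± 0.32 on the log2 scale (adjusted p = 0.0268), as did the Cf2/Cf5 homolog (0.72 ± 0.20) and superoxide dismutase (0.43 ± 0.12). The NB-ARC protein (-1.86 ± 0.56), reticuline oxidase (-1.23 ± 0.28), phenylalanine ammonia-lyase (-1.22 ± 0.30), the peroxidase (-1.15 ± 0.26), the other phenylalanine-ammonia lyase spelling (-0.96 ± 0.24) and a GTP1/OBG family protein (-0.83 ± 0.22) responded less. Of the 14 lists tested, camera called 0, at smallest adjusted p of 0.453 for phenylpropanoids and for transport. Without replicate 1 of every group 3 probes passed, without replicate 2 limma called 0, and without Yr08 8. In AVS the response of 0 probes differed between the times by limma, with 39 at an unadjusted p under 0.05.

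In single lines, 3 inoculated arrays were set against 3 mock arrays to see how resistance genes differ in the transcripts they recruit. Yr08 stood apart, with 17 probes higher and 6 lower at 24 h and 13 higher and 21 lower at 48 h. Fitted on only the arrays compared, 6 and 3 passed, with median centring 4 higher and 4 lower at 24 h and 1 and 19 at 48 h, and with cyclic loess 21 higher and 14 lower at 48 h, so that neither count nor balance is stable. At 24 h the putative disease resistance protein rose 14.1-fold (log2 3.81 ± 0.86, adjusted p = 0.00363) and ent-kaurene synthase 9.95-fold (3.31 ± 0.76, detected on 1 of 3 mock arrays), while a beta-1,3-glucanase fell by 1.91 ± 0.54. Across the alternatives the log2 change of ent-kaurene synthase ran from 1.62 to 5.08, so that its size depends on the processing. At 48 h PR protein 10 rose 14.4-fold (3.85 ± 0.65, adjusted p = 2.86e-05) and a peroxidase 3.91-fold (1.97 ± 0.41), and a blue copper-binding protein fell by 3.91 ± 1.00. Over both times PR protein 10 stood lower in Yr08 mock than in AVS mock arrays (-2.02 ± 0.49). In the inoculated arrays of both times Yr08 and AVS did not differ past the threshold (0.51 ± 0.46). The fold therefore does not show a higher inoculated level than in AVS. PR protein 10 also rose in Yr10 at 48 h, 6.42-fold (2.68 ± 0.65, adjusted p = 0.0319).

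Yr17 had 1 probe lower at 24 h, a sugar transporter (-1.97 ± 0.49, adjusted p = 0.0482), and at 48 h 1 higher, a putative membrane protein (1.31 ± 0.35), and 9 lower, among them a thaumatin-like PR protein (-1.24 ± 0.30, adjusted p = 0.00652). Yr15 had 1 lower probe at each time, the named one a protein kinase at 48 h (-1.26 ± 0.31, adjusted p = 0.0418, detected on 1 of 3 inoculated and 2 of 3 mock arrays). In Yr01, Yr05, Yr07 and Yr09 limma called 0 probes at either time, with 44, 39, 20 and 24 at an unadjusted p under 0.05 at 24 h and 17, 22, 11 and 9 at 48 h. With the replicate number within each time as a block, chosen after seeing the data, it called 5 and 2 in Yr05 at 24 h and 48 h, 4 and 1 in Yr09 and 1 in Yr07 at 48 h. In Yr01 at 24 h it called 162 with median centring (5 higher, 157 lower), 9 with cyclic loess and 5 without background correction, so that these counts of 0 depend on the processing. Yr10 had 0 at 24 h, with 39 unadjusted. The highest number of lines that shared a call was 2, for PR protein 10 at 48 h, and 0.0764 of shuffles of the calls shared as much. Responses of line pairs correlated across probes, which are not independent replicates, at a median of 0.401 at 24 h and 0.302 at 48 h (28 pairs). The differences among the 8 lines passed for 0 probes by limma, with 20 and 28 at an unadjusted p under 0.05, so that the larger Yr08 counts are not shown to differ from those of other lines. The Yr08 count at 24 h was 1 without inoculated replicate 1, 12, 8 and 10 without mock replicates 1, 2 and 3, and at 48 h 20 and 18 without inoculated replicates 1 and 2, and 21 without mock replicate 1. At 48 h all 3 Yr08 mock arrays lay at position 2 of the slide and the inoculated arrays at positions 3 and 4, and with the position as a block, estimated from all lines, 24 probes passed. The Yr17 count at 48 h was 25, 1 and 0 without inoculated replicates 1, 2 and 3, and 5 and 6 without mock replicates 1 and 3.

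AVS, which isolate 78 can infect, shows what inoculation does without a matching resistance gene. At 24 h phenylalanine ammonia-lyase rose 5.63-fold (log2 2.49 ± 0.68, adjusted p = 0.0489), the other phenylalanine-ammonia lyase spelling 5.47-fold (2.45 ± 0.54, adjusted p = 0.00779) and a peptide transporter 3.60-fold (1.85 ± 0.46, adjusted p = 0.0226), each with all 3 inoculated arrays above both mock arrays. Values in AVS were also large, without passing, for the histidine amino acid transporter (2.75 ± 0.77, adjusted p = 0.0565), the blue copper-binding protein (2.25 ± 0.69) and reticuline oxidase (2.10 ± 0.64). Across probes the AVS response correlated with the mean of the lines at 0.785. At 48 h a peroxidase (1.46 ± 0.41, adjusted p = 0.0436) and chitinase (0.89 ± 0.24, adjusted p = 0.0333) rose and a putative membrane protein fell (-1.43 ± 0.35, adjusted p = 0.0103), within 3 probes higher and 3 lower, and PR protein 10 stood at 1.92 ± 0.65 (adjusted p = 0.0901).

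The 23 probes of the PR list stood above the other probes in AVS at 48 h (camera adjusted p = 0.00909), with 1 member higher, and so did the 24 probes of that list with its word match corrected (0.00275). Both calls were lost with an estimated correlation (adjusted p = 0.301 and 0.224). At 24 h camera called 0 of the 14 lists, whereas with corrected word matches, chosen after seeing the data, it called the phenylpropanoid list (adjusted p = 0.00138), to which the other phenylalanine-ammonia lyase spelling was added. The correlation with the mean of the lines was -0.0542 at 48 h. Inoculated replicate 1 of AVS at 48 h had the poorest duplicate spots of all arrays (correlation 0.635, next 0.858). Without it or without mock replicate 2 limma called 0 probes at 48 h, and without inoculated replicates 2 and 3 it called 21 and 23. At 24 h it called 0 without mock replicate 2 or inoculated replicate 1.

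The lines were compared with AVS to separate recognition of an avirulent isolate from inoculation as such. At 24 h limma called 0 probes, with 11 at an unadjusted p under 0.05. In the response of the lines minus that of AVS the oxidative burst list (camera adjusted p = 0.0301) and the transport list (0.0198) stood below the other probes, with no member past the threshold, and both calls were lost with an estimated correlation (adjusted p = 0.0752). With corrected word matches the phenylpropanoid list did so too (0.00368, against 0.0656 as planned). At 48 h 6 probes passed. A putative membrane protein responded more in the lines, by 1.70 ± 0.37 (adjusted p = 0.00504; 0.27 in the mean of the lines and -1.43 in AVS), as did a histidine amino acid transporter (1.07 ± 0.29) and a Ca binding protein (0.86 ± 0.24). A zinc finger DNA binding protein responded less (-1.71 ± 0.44, adjusted p = 0.0265, detected on 16 of 27 inoculated and 15 of 27 mock arrays). The remaining 2 probes, without homology (-1.79 ± 0.41 and 1.93 ± 0.54), were chosen after their values were seen. Without the AVS array of poorest duplicate spots limma called 0, with the membrane protein at 1.32 ± 0.39 (adjusted p = 0.110) and the histidine transporter at -0.00035, and without replicate 1 or 3 of every group it called 1 and 0. Most lines received another isolate than AVS, so that this comparison does not separate the isolate from the resistance gene.

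Yr05 and Yr15 were inoculated with the isolate number used on AVS, which removes that difference. At 24 h their response differed from that of AVS in 0 probes by limma, with 7 at an unadjusted p under 0.05. At 48 h the putative membrane protein passed (1.72 ± 0.42, adjusted p = 0.0392), and leaving out single arrays gave 0 to 18 probes, the latter without AVS inoculated replicate 2.

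The mock arrays at 48 h and 24 h (27 against 26) show the panel under dew and cold darkness and after transfer to light, without the fungus. Under quantile normalization 75 probes were higher and 70 lower at 48 h, more than changed with inoculation, while with median centring 138 passed against 193 and 145 with inoculation, so that this ranking depends on the scaling. HGA1 protein rose 10.2-fold (log2 3.35 ± 0.15, adjusted p = 1.02e-32) and the phenylalanine ammonia-lyase spellings 6.36-fold (2.67 ± 0.16) and 6.01-fold (2.59 ± 0.20). Beta-amylase, which degrades starch, rose by 1.52 ± 0.22, and a protein kinase, detected on 19 of 27 arrays at 48 h and 2 of 26 at 24 h, by 2.11 ± 0.19. The background at 24 h limits the size of the kinase's rise, which ran from 1.07 to 4.04 across the alternatives. An ankyrin-like protein fell by 3.46 ± 0.17, the water-stress protein ERD1 by 3.19 ± 0.19, a UDP-glucosyl transferase by 3.06 ± 0.23, an amino acid permease by 2.54 ± 0.15 and a basic helix-loop-helix protein by 2.01 ± 0.23.

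In the lists of the time comparison, the NBS-LRR list had 4 higher and 0 lower of 12, phenylpropanoids 4 higher and 1 lower of 14, the PR list 1 higher and 8 lower of 23, and terpenes and cytochrome P450 0 higher and 5 lower of 8. Kinases had 6 higher and 4 lower of 24 and transport 2 higher and 4 lower of 17. Camera called 0 of the 14 lists (smallest adjusted p = 0.355, PR list), while fry, which asks whether a list moved in a common direction without regard to other probes, called 11. Its test for members that moved in either direction called 4. Median and camera direction differed in sign for the oxidative, calcium, transcription factor and study lists. At an absolute log2 change of at least 1, 47 probes passed. Within positions 1 to 4 of the slide 138, 127, 130 and 143 of the 145 probes had the pooled direction, which was taken from the same arrays.

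The mock arrays of each line (6) were set against those of AVS (5) to ask how far near-isogenic lines differ without inoculation. A hydroxyproline-rich glycoprotein, of the family of structural wall proteins, was higher in Yr05 (log2 5.11), Yr07 (5.24), Yr08 (4.06), Yr15 (5.35) and Yr17 (5.25), each ± 0.61, with adjusted p from 1.06e-06 to 4.27e-11. Except in Yr08 its mean over the mock arrays of these lines, 15.26 to 15.51, lay near the highest normalized value of any probe (15.67), so that the ceiling limits these differences. It was detected on 6 of 6 mock arrays of each of these lines and on 3 of 5 of AVS. In Yr08 methionine-S-oxide reductase was lower (-1.31 ± 0.30, adjusted p = 0.00166), and in Yr17 a pathogen-induced secretory protein was higher (2.12 ± 0.60, adjusted p = 0.025). The probe described as putative stripe rust resistance protein Yr10 stood at 0.08 ± 0.33 in Yr10 (adjusted p = 0.991).

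Probes without a gene name were chosen after their values were seen. A hypothetical protein was lower in Yr09 (log2 -5.73 ± 0.24) and Yr15 (-5.70 ± 0.24), where it was detected on 2 and 1 of 6 arrays, while its AVS mean of 15.44 lay near the top of the scale, so that both ends of the scale limit these differences. A probe without homology was higher in Yr05 (4.22), Yr07 (4.01) and Yr10 (4.15), each ± 0.39. It was detected on 1 of 5 AVS mock arrays, so that the background limits these differences. Counts of probes that passed were 4 in Yr01, 12 in Yr05, 6 in Yr07, 18 in Yr08, 1 in Yr09, 1 in Yr10, 3 in Yr15 and 12 in Yr17. Since all lines share the AVS arrays, unchanged lines were simulated against them, and at most 2 lines then shared a probe, in 2 of 100 simulations, against 5 lines observed for the hydroxyproline-rich glycoprotein. Of 57 pairs of probe and line, 55 had the same direction in the inoculated arrays and 26 also passed there. With median centring Yr01 had 67 (65 higher, 2 lower) and Yr05 7, on only the arrays compared Yr08 had 3, and with the replicate number within each time as a block Yr05 had 22, Yr07 10, Yr08 40 and Yr17 23. The counts also moved by more than 1.5 times with single arrays left out in Yr01 (0 to 12), Yr07 (2 to 14), Yr08 (11 to 42), Yr09 (1 to 6), Yr10 (1 to 2), Yr15 (2 to 11) and Yr17 (7 to 18).

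**Figure D3:**
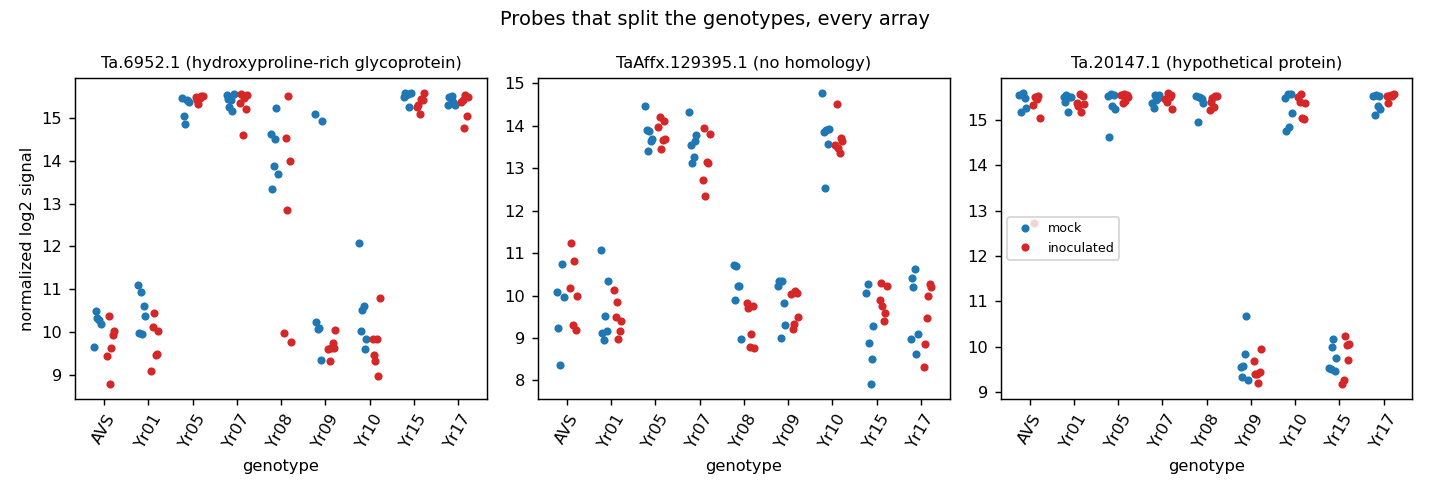
Normalized log2 signal of 3 probes on every array by genotype, mock in blue and inoculated in red. The hydroxyproline-rich glycoprotein (left) runs from 9.77 to 15.51 within Yr08, while the probe without homology (middle) and the hypothetical protein (right) split the genotypes without overlap.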

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

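The tests of array brightness, position on the slide, single Yr08 arrays and the AVS array of poorest duplicate spots on single probes were chosen only after the result was seen, and the others were written down first.

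In the mean of the 8 lines at 24 h 79 probes passed while inoculated arrays were brighter, at a mean log2 of 14.35 against 13.73. Array brightness as the whole source is argued against by 72 of the 79 probes that passed in the same direction with brightness as a covariate, and the position on the slide by 77 that did so with the position as a block. Chance as the source of the count is argued against by other splits of the same arrays, which gave at most 13 (1 of 100 splits reached 79, the real one). That is the smallest share these splits can give, and its bound was not adjusted over the comparisons. A response to inoculation stays open as a hypothesis, found and tested on the same arrays. The direction of small changes stays open too, since with median centring 32 probes were higher and 161 lower.

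Yr08 had more probes past the threshold than any other line, 23 at 24 h and 34 at 48 h. The position on the slide is argued against, as far as its effect is common to all lines, by 22 probes at 24 h and 24 at 48 h with the position as a block, and a single array by changes that stayed at a median of at least 89.6% at 24 h (81.6 to 92.8) and 96.4% at 48 h (87.6 to 99.6) with any 1 array left out. The count at 24 h still fell to 1 without inoculated replicate 1, but was 34 without inoculated replicate 2. The median SE rose from 0.57 to 0.64 either way, so that the count leans on inoculated replicate 1. At 24 h atypical Yr08 mock arrays also remain, which hold 90.2% (75.1 to 144) of the excess over the other lines. At 48 h the mock arrays hold 4.39% (-1.15 to 48.4) of the excess, and atypical mock arrays cannot be told apart from a stronger response because of that spread, nor is a position effect particular to Yr08 tested, since its 3 mock arrays lay at position 2 and its inoculated arrays at 3 and 4. The ranges in brackets were taken over the probes that passed, on the same arrays, so that they do not measure the spread between arrays. For Yr08 at 24 h and at 48 h the splits are too few for a share under 0.05 (real 23, highest other 3, and real 34, highest other 6, each in 1 of 10 splits).

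The response at 48 h differed between the lines and AVS in 6 probes, which was marked because the difference itself was tested. The array with the poorest duplicate spots is argued against as the source for 5 probes, whose difference stayed at a median of 95.2% without it, although limma then called 0 of them (unadjusted p from 0.000338 to 0.0105). For the histidine amino acid transporter -0.0327% stayed, so that its difference rested on that array. Across probes the AVS response correlated with the mean response of the lines at -0.253 without the array and -0.0542 with it, so that the array is not why it did not correlate with that mean. With single lines, on all arrays, the correlation ran from -0.395 for Yr17 to 0.249 for Yr15 (median 0.0327). Chance is not excluded, since 13 of 100 splits gave 6 or more (highest other 12), and a difference between compatible and incompatible interactions stays open, untested against the isolate in most lines.

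A tested difference between groups also marked 1 probe for Yr05 and Yr15 minus AVS at 48 h, where chance is not excluded (61 of 100 splits, highest other 16, which points to a structure of the samples that was not tested). The difference between 48 h and 24 h in the lines was marked for the same reason, with 15 probes (1 of 100 splits, the real one, highest other 6). Chance is not excluded, since the bound was not adjusted over the comparisons and few or no probes passed without replicate 1 or 2 of every group. Spots that should hold no wheat target gave signal above the background spots. The median log2 above them was 2.02 for blank buffer (above background on 85 arrays, inoculated minus mock 0.30), 3.04 for the bacterial control THRX, 4.33 for PHEX (103 arrays) and 4.31 for DAPX, but 0.17 for LYSX (8 arrays).

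Among the other comparisons, the splits argue against chance, at a bound not adjusted over the comparisons, for the mean of the lines at 48 h (real 43, highest other 12, 1 of 100 splits) and for mock at 48 h against 24 h (145, highest other 39, 1 of 100). For mock arrays against AVS mock a share under 0.05 of the splits reached the real count in Yr05 (12, highest other 15, 2 of 100 splits), Yr07 (6, 5, 1), Yr08 (18, 27, 4) and Yr17 (12, 6, 1). That bound was applied line by line without adjustment over the 8 lines, so that chance is not excluded for the counts of these lines. In Yr05 and Yr08 another split also gave more probes than the real one. Nor is chance excluded for the counts of Yr01 (4, 34, 11), Yr09 (1, 5, 32), Yr10 (1, 7, 39) and Yr15 (3, 22, 8), and the splits of Yr01, Yr10 and Yr15 with several times the real count point to a structure of the samples. A count cannot judge a single large difference. In the inoculated arrays the probes of Yr09 (-5.40 ± 0.22), Yr10 (3.59 ± 0.37) and Yr15 (-5.18, 5.66 and -1.26) all passed in the same direction. This argues against chance for these probes, while in Yr01 only a protein kinase (0.94) did so. Where limma called 0, all 100 of 100 splits give at least as many by construction, so that the share says nothing about chance. The highest other splits were 3 for the lines minus AVS at 24 h, 6 for Yr05 and Yr15 minus AVS at 24 h, 18 and 7 for differences among the lines at 24 h and 48 h, and 11 for the time difference of AVS. These 5 had 11, 7, 20, 28 and 39 probes at an unadjusted p under 0.05.

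For single lines against their mock arrays the splits number 10 and are too few for a share under 0.05. At 24 h the real count and the highest other split were 0 and 12 in Yr01, 0 and 5 in Yr05, 0 and 0 in Yr07, 0 and 11 in Yr09, 0 and 0 in Yr10, 1 and 0 in Yr15 and 1 and 0 in Yr17. At 48 h they were 0 and 7 in Yr01, 0 and 1 in Yr05, 0 and 2 in Yr07, 0 and 1 in Yr09, 1 and 6 in Yr10, 1 and 0 in Yr15 and 10 and 9 in Yr17, and in AVS 6 and 12. Of the 10 splits, 4 gave as many as the real one in AVS at 48 h and in Yr10 at 48 h, 1 in Yr15 and Yr17 at both times, and, by construction, 10 wherever limma called 0. Of the other splits of single genotypes, 14 follow the position on the slide, of which 8 gave 0 probes, and 139 do not, of which 99 gave 0. In Yr10 at 48 h 2 splits gave 6 probes, of which 1 parts the 3 arrays at position 1 from the other 3 and 1 follows no position, and with the position as a block 1 probe passed. In Yr09 at 24 h a split along the position gave 7 and another 11, and in Yr17 at 48 h a split along the position gave 6 and others 7 and 9. The splits with several times the real count in Yr10 at 48 h point to a structure of the samples, and only 1 of them follows the position. Whether the splits follow the replicate number, which the splits do not keep together, was not tested.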

How the results depend on the processing

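Fits with the position block, the replicate block by time, array brightness, array weights, the poorest array left out and Yr08 left out, the probe classes, and gene lists with corrected word matches, were chosen only after the results were seen, and the others were planned. Of the named results past the threshold, 80 did not stay past it in the same direction under every alternative run on them and 27 did, among them 1 probe of each phenylalanine ammonia-lyase spelling, the heat-stress transcription factor and alternative oxidase at 24 h, and ent-kaurene synthase and PR protein 10 at 48 h in the mean of the lines. For the results listed by value below, the cause was not tested, except that settings with fewer arrays or probes have fewer to test. Counts are probes past the threshold, and comparisons not listed under a setting stayed within 1.5 times their count. The median of the 2 spots equals their mean, so that this setting could move none of the 38 counts and tests nothing. Dim probes are limited by the signal, since 213 to 350 of 355 probes per array lay above the background spots, and the NB-ARC protein did so on 79 arrays and ent-kaurene synthase on 78.

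Without background correction the count was 13 for AVS at 48 h, 5 for Yr01 at 24 h, 2 for Yr10 at 24 h and 1 for Yr09 at 48 h. It was 0 for Yr10 and Yr15 at 48 h and for Yr05 and Yr15 minus AVS at 48 h, 6 for the time difference of the lines, and 1 and 2 for Yr01 and Yr09 mock against AVS mock.

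With median centring the mean of the lines had 193 at 24 h and 145 at 48 h, against 79 and 43, and Yr01 had 162 at 24 h, where the median of all probes moved by -1.26. Yr08 had 8 at 24 h and 20 at 48 h, Yr17 8 at 24 h and 0 at 48 h, and Yr15 0 at both times. AVS had 0 at both times, and so had Yr10 at 48 h, the lines minus AVS at 48 h and Yr05 and Yr15 minus AVS at 48 h. The time difference of the lines had 5, Yr01 mock against AVS mock 67 and Yr05 mock against AVS mock 7. In the mean of the lines at 48 h, 3 probes turned below 0, WIR1B to -0.25, chitinase to -0.20 and a WIR1A probe that had not passed to -0.43.

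With cyclic loess AVS had 1 at 24 h and 10 at 48 h, Yr01 9 and 3, Yr05 1 and 4, and Yr17 10 and 0. Yr15 at 24 h and Yr10 at 48 h had 0. Yr05 and Yr15 minus AVS at 48 h had 3, and the mock comparisons with AVS had 1 for Yr01, 30 for Yr08 and 26 for Yr17.

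With the deposited log2 values AVS had 1 at 24 h and 14 at 48 h, Yr05 3 and 4, Yr17 3 at 24 h, Yr07 1 and Yr15 0 at 48 h. Differences among the lines at 24 h had 2, the lines minus AVS at 48 h 11 and the time difference of the lines 7.

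Without the dimmest probes the mean of the lines at 24 h had 49, Yr17 at 24 h 2, Yr15 at 48 h 0 and the time difference of the lines 9. Mock arrays against AVS mock had 0 in Yr01, 6 in Yr05, 11 in Yr08 and 0 in Yr10. With an absolute log2 change of at least 1 as a further condition, the mean of the lines had 17 at 24 h and 5 at 48 h. Yr17 at 48 h then had 3, the time difference of the lines 6 and mock at 48 h against 24 h 47.

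Fitted on only the arrays compared, Yr08 had 6 at 24 h and 3 at 48 h. AVS at both times, Yr15 and Yr17 at both times, Yr10 at 48 h and Yr05 and Yr15 minus AVS at 48 h had 0. The lines minus AVS at 48 h had 3. Mock against AVS mock had 0 in Yr01, 2 in Yr07, 3 in Yr08 and 30 in Yr17, and the most lines that shared a call was 1.

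Replicate numbers were not taken to pair the arrays. Of 53 pairs of mock and inoculated arrays with the same number, 32 deviated from their group means with a correlation above 0.1 (lowest -0.234), and in 4 of 18 comparisons all pairs did. As a hint from the data, 85 arrays correlated best with arrays of their own number, and the mean correlation was 0.155 with the same number against -0.0768 with another. With the replicate block AVS at 24 h had 5, Yr05 1, Yr09 1 and Yr17 2 at 24 h, and Yr05 and Yr08 mock against AVS mock 19 and 36. No other count moved beyond 1.5 times with it. With the replicate block by time AVS at 24 h had 8, Yr05 5 and 2 at 24 h and 48 h, Yr09 4 and 1, Yr17 5 at 24 h and Yr07 1 at 48 h. Yr05 and Yr15 minus AVS at 48 h had 2, and mock against AVS mock had 22 in Yr05, 10 in Yr07, 40 in Yr08 and 23 in Yr17.

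The position on the slide as a block gave 2 for Yr15 at 24 h and 0 for Yr05 and Yr15 minus AVS at 48 h, and left the other 36 counts within 1.5 times. Array brightness as a covariate gave 121 and 71 for the mean of the lines at 24 h and 48 h, 47 and 73 for Yr08, and at 24 h 18 for Yr01, 3 for Yr05, 8 for Yr10 and 1 for differences among the lines. Mock against AVS mock had 2 in Yr01, 9 in Yr09 and 5 in Yr15 with it. Without the array of poorest duplicate spots AVS at 48 h, the lines minus AVS at 48 h and Yr05 and Yr15 minus AVS at 48 h had 0, the time difference of AVS 2, and the histidine amino acid transporter turned from 1.07 to -0.00035. Without Yr08 the mean of the lines had 50 at 24 h and 15 at 48 h, and the time difference 8.

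With array weights, whose estimation stopped before reaching its tolerance and the lowest of which was 0.191, 24 of 38 counts moved beyond 1.5 times. AVS at 24 h had 6, Yr08 48 and 55 at 24 h and 48 h, Yr10 3 and 8, Yr17 26 and 59, and Yr15 2 at 24 h. At 48 h Yr01 had 5, Yr05 14 and Yr07 1, and the mean of the lines 70. Differences among the lines had 10 and 49, the time difference of the lines 36, that of AVS 5, and Yr05 and Yr15 minus AVS at 48 h 0. Mock against AVS mock had 16 in Yr01, 28 in Yr05, 18 in Yr07, 76 in Yr08, 5 in Yr09, 26 in Yr15 and 63 in Yr17.

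With an estimated correlation the transcripts named by the study at 24 h lost their camera call (adjusted p = 0.194), and so did the class for the hypersensitive response to Yr5 at 48 h (0.0948), the PR list in AVS at 48 h (0.301), and oxidative burst and transport in the lines minus AVS at 24 h (both 0.0752; 0.0501 and 0.0418 with corrected word matches, where transport stayed past the threshold with the same members). With corrected word matches no list gained or lost a camera call in the mean of the lines (PR list 0.521 and 0.198 at 24 h and 48 h, NBS-LRR 0.218 and 0.498, phenylpropanoids 0.118 at 24 h), but phenylpropanoids gained one in AVS at 24 h (0.00138, and 0.0202 with an estimated correlation) and in the lines minus AVS at 24 h (0.00368 and 0.0384). In the mean of the lines, fry's test for members that moved in either direction called 0 of 14 lists at both times. Its test for a common direction, which compares no list with other probes, called more. At 24 h its adjusted p was 0.0132 for phenylpropanoid and lignin, 0.00442 for NBS-LRR resistance proteins, 0.00897 for calcium signalling, 0.0023 for transcription factors, 0.000517 for protein turnover, 0.000375 for cell wall and 1.39e-05 for reference genes. At 48 h it was 0.00362 for terpenes and cytochrome P450, 0.0106 for protein turnover, 0.000957 for reference genes and 0.00362 for the transcripts named by the study.

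With single replicates left out in turn, where an arm of 1 array is assumed to vary like the other groups, the mean of the lines had 35 to 73 at 24 h and 2 to 79 at 48 h. AVS had 0 to 4 at 24 h and 0 to 23 at 48 h, Yr08 1 to 34 and 18 to 31, and Yr17 0 to 1 and 0 to 25. Yr01 had 0 to 9 and 0 to 3, Yr05 0 to 14 and 0 to 4, Yr07 0 to 1 and 0 to 2, and Yr09 0 to 3 and 0 to 2. Yr10 had 0 to 1 and 0 to 7, and Yr15 0 to 1 at both times. The lines minus AVS at 48 h had 0 to 9, Yr05 and Yr15 minus AVS at 48 h 0 to 18 and differences among the lines at 48 h 0 to 7. The time difference had 0 to 17 in the lines and 0 to 7 in AVS. Mock against AVS mock had 0 to 12 in Yr01, 2 to 14 in Yr07, 11 to 42 in Yr08, 1 to 6 in Yr09, 1 to 2 in Yr10, 2 to 11 in Yr15 and 7 to 18 in Yr17. The most lines that shared a call was 1 to 3.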

Other observations

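Tests on the probe classes that the array's own names give and on genotype identity were chosen only after the files had been read. The test of the isogenicity class probe by probe and the division of the genotype test at a log2 difference of 2 were chosen only after the result was seen, as were the probes named here.

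The probe names of the array also give classes tied to Yr5 and Yr39. The class for the hypersensitive response to Yr5, of 52 probes, stood above the other probes in the mean of the 8 lines, with 12 higher and 2 lower at 24 h (camera p = 0.00394) and 12 higher and 3 lower at 48 h (camera p = 0.0213, adjusted p = 0.0355), although the latter call was lost with an estimated correlation (adjusted p = 0.0948). Of 89 probes of the class named HTAP-specific for Yr39, 17 were higher and 7 lower at 24 h (adjusted p = 0.00796) and 10 and 4 at 48 h (0.136). Of 90 probes of the class named Pst-induced for Yr39, 6 were higher and 4 lower at 24 h (camera adjusted p = 0.47) and 6 and 1 at 48 h (0.0355). The basal defense class of 47 probes had 8 higher and 3 lower at 24 h (camera adjusted p = 0.199) and 2 and 2 at 48 h (0.797), and in AVS at 24 h it stood above the other probes (adjusted p = 0.0226).

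The class for incomplete isogenicity with Yr5, of 69 probes, stood below the other probes in the mean of the lines, with 2 higher and 14 lower at 24 h (camera p = 4.83e-06) and 1 and 4 at 48 h (p = 0.000266), both also called with an estimated correlation (adjusted p = 0.00278 and 0.0206). No explanation was tested for this place. In Yr05 mock against AVS mock 8 of its 69 probes passed, against 4 of 286 other probes (exact Fisher test, one-sided p = 0.000363). The same loci in all lines, probe by probe, are argued against by the inoculated arrays, where all 8 differed between Yr05 and at least 1 other line in the same direction. The class over the other lines, with 9 of 69 against 26 of 286 (exact Fisher p = 0.218), decides nothing, since a p that misses the threshold shows no absence of a difference and the bound set for it was wrong, and Yr07 alone had 4 against 2 (exact Fisher p = 0.0145). Loci linked to Yr05 from the donor cannot be told apart from loci shared by some lines, since 5 of the 8 probes also passed in the same direction in 1 to 4 other lines and 3 in Yr05 alone. All 3 were lower in Yr05 mock arrays (-3.79, -3.22 and -0.55), and the probe at -3.22 was undetected on 6 of 6 inoculated Yr05 arrays, at least 7.04-fold lower than in inoculated AVS.

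Whether the mock differences follow the genotype was tested in the inoculated arrays, where 55 of 57 pairs of probe and line had the same direction and 26 also passed (45.6%). For pairs with a log2 difference of at least 2 in mock, 16 of 21 did so (76.2%), but these pairs are not independent, since all share the AVS arrays and 3 probes make up 10 of the 16, and of the 14 distinct probes 9 passed in at least 1 line (64.3%). For the smaller differences 10 of 36 pairs did so (27.8%, binomial interval 14.2 to 45.2 if they were independent). Genotype cannot be told apart from other causes for the pairs as a set, of either size, since a share or its interval lies between the bounds written down for either reading. By the 25 probes that differ most between genotypes, picked on the same arrays, 98 arrays lay closest to their own genotype and 9 to another, of which 6 were AVS arrays closest to Yr01 or the reverse, genotypes that these probes hardly separate, so that exchanged labels between AVS, the reference of every mock comparison, and Yr01 are not ruled out. The others were 2 Yr09 mock arrays closest to Yr15 and an inoculated Yr08 array closest to AVS. Without the hydroxyproline-rich glycoprotein these lay closest to their own genotype, and 10 arrays lay closest to another. Among the 10 were a Yr09 array closest to Yr15 and a Yr15 array closest to Yr09, both closest to their own genotype with all 25 probes. That Yr09 array stood at 9.75 for the hydroxyproline-rich glycoprotein, against 15.11 to 15.59 in Yr15. This argues against its exchange with a Yr15 array. For the Yr15 array, at 15.59, an exchange is not ruled out by this probe, since 2 Yr09 mock arrays also stood high. The hydroxyproline-rich glycoprotein was uneven within lines, as it stood at 15.09 and 14.94 on 2 Yr09 mock arrays against a mean of 10.65 over the line, and ran from 9.77 to 15.51 in Yr08, against means of 15.36, 15.34, 15.43 and 15.34 in Yr05, Yr07, Yr15 and Yr17 and of 9.92, 10.13 and 10.08 in AVS, Yr01 and Yr10. As a hypothesis, seed of Yr08 and Yr09 may not be uniform for this locus. Its fall in the mean of the lines at 24 h (-0.92 ± 0.29) was -0.52 ± 0.33 without these 2 lines, and at 48 h -0.35 against -0.03.

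In Yr08 mock arrays of both times PR protein 10 stood lower than in AVS mock (-2.02, adjusted p = 0.00364), while in the inoculated arrays it differed by 0.51 (adjusted p = 0.445). No explanation was tested for this difference.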
